A study of Triticum aestivum with 7 samples.

How the data were processed

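Small RNAs from spikes of wheat were measured in 7 libraries, 3 from cold-treated and 4 from control plants. Per the labels' protocols, about 20 spikes from primary stems were pooled per stage, total RNA was extracted with TRIzol, and RNAs of 16 to 30 nt were selected by size before library construction. The deposited files hold, per the file headers, a length, a count and a sequence in each line. The counts as deposited are whole numbers of reads for each distinct sequence of 18 to 30 nt and were not normalized for depth. The sequencing platform, adapter trimming, read filters, aligner and genome build are not given in the sources used here. Trimming that removes too many or too few bases, or a filter on read quality, would move reads between length classes and between forms of a miRNA. No genome was used, so tags are given by sequence and the positions of loci were not analysed here. A table of wheat gene names that came with the reference holds no miRNA genes and was not used.

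Reads were assigned to 38 families (69 reference sequences of conserved plant and cereal miRNAs and tasiR-ARF, written from general knowledge before the data were examined). A read of 18 to 25 nt was counted for a family when it held bases 3 to 18 of a reference without mismatch, starting no more than 4 bases from the 5' end of the read. Members of a family share this core, so a family value sums over the gene copies of the 3 wheat subgenomes, which cannot be told apart. Of the 38 families, 3 had 0 reads under this rule, and the rule depends on the reference chosen. Families were tested where at least 1 library of the fit had 10 RPM or more. Tags were distinct sequences of 20 to 24 nt with at least 10 RPM in at least 2 libraries. Fragments were reads of at least 18 nt found inside 8 listed tRNA and rRNA sequences.

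Depth ran from 7.42 to 12.5 M reads per library. RPM (reads-per-million) are counts divided by all reads in the library and scaled. Tests used edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided) with the total reads as library size and Benjamini-Hochberg adjustment, at a threshold of 0.05. The standard error of a log2 value is the value divided by the square root of its F statistic. Cold was tested over 6 libraries with the stage as a factor, which left 2 residual degrees of freedom. The trend with anther length was tested over 7 libraries with cold as a covariate (4 degrees of freedom) and the interaction of cold and length over the same 7 (3 degrees of freedom). The spread in these tests is that between stages around the model, since no stage and treatment was repeated. The p-values thus say nothing about variation between plants at 1 stage. edgeR partly pools this spread over all families or tags of a fit. A standard error or p-value therefore does not rest on the ratios of that family or tag alone. Within a stage, ratios carry exact conditional binomial 95% intervals for counting error, and a family was called at least 2-fold different where the whole interval lay beyond 2-fold and 1 of the libraries had 10 RPM. Shares were compared by an exact permutation test that flips the signs of the 3 stage differences. Reads amplified by PCR without molecular identifiers are not independent molecules, so all intervals cover counting error only.

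The tests were checked on simulated counts with the means, dispersions and library sizes of these libraries. For cold, 48.0% of families and 26.9% of tags changed 2-fold were recovered, and 99.0 and 97.3% of those changed 4-fold. For a change over the range of anther lengths, 31.0% of families at 2-fold and 92.0% at 4-fold were recovered, and 8.06 and 68.4% of tags. For the interaction, 28.0% of families at 4-fold and 64.0% at 8-fold were recovered.

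The families and tags named were set by a rule written before the data were examined. It takes all families past the threshold, at most 15 in each direction. Where fewer than 10 pass, it adds the families with the largest ratios among those at 10 RPM or more whose ratios have the same sign at all 3 stages, up to 20, as values that did not pass. It takes up to 8 families at least 2-fold different within a stage, and always miR2118, miR2275, miR390 and tasiR-ARF. Of the tags it takes up to 5 in each direction. Families were grouped in lists fixed at the same time (auxin, development, copper and laccase, nutrient, stress, small RNA pathway, MADS, reproductive phased small RNA triggers and cereal families), and other members were named as examples of their lists after their values were seen. Alternatives set before the data were examined were TMM factors, DESeq2 size factors, family reads or reads without fragments as the library size, DESeq2 1.42.0, other filters and matching rules, other model terms, and each stage pair or library left out in turn. Alternatives chosen after seeing the data were fits without, or with a term for, the 2 control libraries that share the error at position 12, a wheat start for the 5.8S rRNA fragment, and distinct sequences at equal depth.

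The change at position 12 was counted in 10 leading sequences of 20 nt or more from the most abundant listed families, 3 of which have A there, among reads that match the sequence or differ by that base, and again in the 100 most abundant other tags with A there. Principal components were taken of log2 RPM plus 1 over 7589 tags. Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9 were used for counting, exact tests and plots.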

Results

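Small RNA was sequenced from young spikes of a thermosensitive genic male sterile line of bread wheat (Triticum aestivum), a kind of line in which pollen formation depends on the temperature the plant meets. Cold-treated plants and control plants were compared while the anthers grew. There were 7 libraries: 1 control library at an anther length of 1.0 mm, and 1 cold and 1 control library at each of 1.5, 2.2 and 3.0 mm. Per the labels' protocols, secondary sporogenous cells had formed at 1.5 mm, the anther layers were complete at 2.2 mm and meiosis was under way at 3.0 mm. The tissue was the spike, and the libraries do not separate the anthers from its other parts. Each library was made from about 20 spikes, and no stage and treatment had a second library.

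The libraries held between 7.42 M reads (control, 1.5 mm) and 12.5 M reads (control, 2.2 mm), 77.5 M in all. Distinct sequences numbered from 2.91 M in the control library at 1.5 mm to 5.18 M in the control library at 2.2 mm. Of the distinct sequences in a library, 74.1 to 82.0% were read once. The 38 listed families of conserved plant and cereal small RNAs took 3.35 to 4.48% of the reads. miR168, which targets the Argonaute gene AGO1, was the most abundant of them, at 12700 to 16550 RPM (reads per 1e6, of all reads in the library), followed by miR166, which targets class III homeodomain genes of organ polarity, at 7488 to 11810 RPM. miR167 had 4255 to 6147 RPM and the cereal family miR9672 had 3478 to 5001.

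Reads of 24 nt, the usual length of heterochromatic small interfering RNAs, were the largest class in each library. They made up 53.3% of the reads in the control library at 1.0 mm. In the pairs of cold and control libraries their share was 64.9 and 51.1% at 1.5 mm, 58.0 and 61.2% at 2.2 mm, and 59.6 and 59.5% at 3.0 mm. Reads of 21 nt, the length of most miRNAs, made up 25.8% at 1.0 mm, and 15.4 and 22.9% in cold and control at 1.5 mm, 19.0 and 16.5% at 2.2 mm, and 19.2 and 18.3% at 3.0 mm. Reads of 22 nt had a lower share in cold at each stage, with cold minus control differences of -0.356, -0.835 and -0.629 percentage points at 1.5, 2.2 and 3.0 mm.

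The shares were compared by sign flips of the 3 stage differences, for which the smallest exact permutation p possible is 0.25 (two-sided), so this test cannot pass the threshold. That p was 0.25 for the 22 nt share (mean difference, cold minus control, -0.606 ± 0.24 percentage points, SD, n = 3 pairs), 0.75 for the 24 nt share (3.59 ± 9.02) and 1.00 for the 21 nt share (-1.38 ± 5.40). Without the 1.5 mm pair the mean difference was -1.53 points for 24 nt and 1.71 points for 21 nt reads, so both changed sign. The share of reads in the listed families was lower in cold at all 3 stages, with differences of -0.870, -0.048 and -0.119 points (exact permutation p = 0.25). Fragments of 6 tRNAs and 2 rRNAs, included as signs of RNA breakdown, took 1.14 to 1.54% of the reads, with cold minus control differences of -0.305, 0.167 and -0.155 points (exact permutation p = 0.75). With a wheat start of the 5.8S rRNA added to the list they took 2.22 to 3.16%, and the mean difference went from -0.098 to -0.298 points. Distinct sequences per read differed by 3.41, -2.10 and -1.19 points (exact permutation p = 1.00), and by 6.46, -2.83 and -0.373 points at an equal depth of 7.42 M reads (exact permutation p = 1.00). The 24 nt share of the shallowest library, the control at 1.5 mm, had a 95% Wilson interval of 51.04 to 51.11%, which is about as wide as the 24 nt difference of 0.078 points at 3.0 mm.

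**Figure D1:**
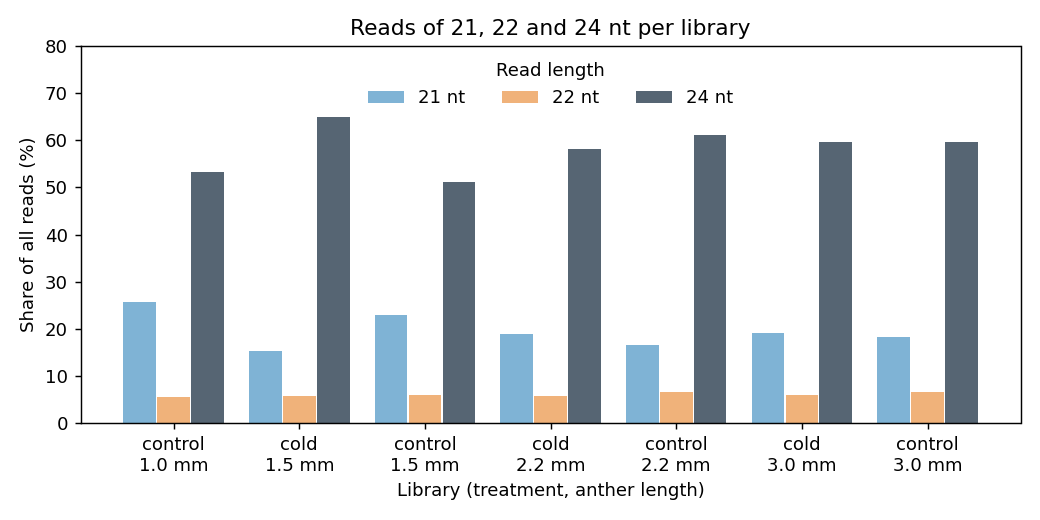
Share of all reads (%, vertical axis) that were 21, 22 or 24 nt long in each of the 7 libraries, 1 bar per length and library. The 24 nt share was lowest in the control library at 1.5 mm (51.1%) and highest in the cold library at 1.5 mm (64.9%).

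The first base differed between the length classes as it commonly does in plants. Adenine began 49.9 to 53.7% of the 24 nt reads, and thymine (uracil in the RNA) began 42.7 to 48.1% of the 21 nt reads. Guanine began 22.6 to 25.1% of the 24 nt reads and cytosine 6.62 to 8.46% of them. No test was run on these shares.

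The first comparison asked which small RNA families differed between cold and control over the 3 stages that had both. No family passed the test: 0 of 22 families fell or rose at an adjusted p below 0.05 in edgeR's quasi-likelihood test with the stage as a factor, 0 had an unadjusted p under 0.05, and the lowest adjusted p was 0.824. DESeq2's Wald test called 0 families as well, with 2 at an unadjusted p under 0.05. The result depended on the 3.0 mm pair: without it 0 of 22 passed but 6 had an unadjusted p under 0.05, and miR528, miR390 and miR393 had estimates of -0.59, -0.84 and -0.83 (edgeR adjusted p = 0.0530, 0.0643 and 0.0744). The cold libraries nevertheless had lower values for most families at the earliest stage. Against the control library, 20 of the 22 families were lower in the cold library at 1.5 mm, 15 at 2.2 mm and 12 at 3.0 mm, with median log2 ratios of -0.62, -0.20 and -0.02. With listed family reads as the library size, 17, 14 and 8 were lower, with medians of -0.28, -0.18 and 0.02. At 1.5 mm the cold library also had the higher 24 nt share, and its control carried a sequencing error described below, which the pairs at 2.2 and 3.0 mm lacked. Short reads differed in this pair as well: 18, 19 and 20 nt reads made up 1.15, 1.88 and 2.82% in cold and 3.804, 4.40 and 5.15% in control.

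The 5 tested members of the auxin list (miR164, miR167, miR390, miR393 and the TAS3-derived tasiR-ARF) all had estimates below 0, as did 19 of all 22 families. None of them passed, also when adjusted over the list alone (0 of 5, lowest edgeR adjusted p = 0.241), and without the 1.5 mm pair the estimate of tasiR-ARF was 0.00. miR167, which targets the auxin response factors ARF6 and ARF8, had log2 ratios of -0.34, -0.22 and -0.39 at the 3 stages (estimate -0.32 ± 0.17, SE, edgeR adjusted p = 0.824). Its 2 leading forms, which differ in their last bases as well as in length, differed in this. The 22 nt form had 3497 RPM in cold and 3615 in control at 1.5 mm, 3150 and 4025 at 2.2 mm, and 3301 and 4429 at 3.0 mm. The 21 nt form had 1031 and 2155, 1274 and 1138, and 984 and 1298 RPM, so it was higher in cold at 2.2 mm. With TMM scaling in place of total reads the miR167 family passed (-0.41, edgeR adjusted p = 0.0426, against 0.0581 to 0.959 under the other alternatives). miR393, which targets the TIR1 and AFB auxin receptors, had 43.0 RPM in cold and 86.1 in control at 1.5 mm, with log2 ratios of -0.67 and -0.06 at 2.2 and 3.0 mm, and miR164, which targets NAC transcription factors, had -0.57, -0.52 and -0.04. miR390, which starts the cutting of TAS3 transcripts, had -1.73, 0.06 and -0.39. tasiR-ARF, a product of that cutting that targets other auxin response factors, had -0.66, -0.02 and 0.02.

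Of the development list, 7 members were tested, and none passed (0 of 7 adjusted over the list alone). Their ratios went both ways at 3.0 mm. miR156 had log2 ratios of -0.67, -0.33 and 0.56, miR172 -0.80, -0.02 and 0.91, and miR396 -0.72, -0.77 and 0.57. The forms of miR396 differed at 1.5 mm, where short reads were fewer in cold. Its leading 21 nt form had 73.4 RPM in cold and 85.3 in control. The leading 18 nt forms had 28.7 and 70.8, and 22.5 and 45.6. miR166 had -0.43, 0.13 and -0.27, miR171 -0.66, 0.14 and 0.42, and miR159 0.16, -0.28 and -0.07. The miR159 values mostly reflect an 18 nt form, with 62.1 RPM in cold and 59.4 in control at 3.0 mm. There the 22 nt form had 6.84 and 8.93 and the 21 nt form 3.38 and 5.79. In the stress list, both tested members were lower in cold at each stage without passing (0 of 2 adjusted over the list alone). miR169, which targets NF-YA transcription factors, had log2 ratios of -0.88, -0.18 and -0.16, and miR393 is given above. miR528, a monocot family whose targets include copper proteins and the 1 tested member of the copper and laccase list, had -0.58, -0.61 and -0.02.

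The nutrient list had 2 tested members, miR399 (-0.73, 0.14 and -0.02) and miR827 (-0.98, -0.43 and 0.79). miR444, a monocot regulator of MADS-box genes, had -1.09, 0.02 and -0.03. miR168 of the small RNA pathway had ratios of -0.13, 0.08 and 0.10 (estimate 0.01 ± 0.13, SE). Among the 5 tested cereal families, 4 had estimates below 0. miR9674 was lower at each stage (-0.33, -0.09 and -0.01), and miR9664 had the highest ratio of the 22 tested families at 1.5 mm (0.67). None of these lists had a member past the threshold, over all families or adjusted over the list alone.

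The triggers of reproductive phased small RNAs were too scarce to be tested for cold. miR2118, which starts 21 nt phased small RNAs in grass anthers, had 1 to 9 reads per library, with a cold to control ratio of 0.680 (exact 95% interval 0.00866 to 53.3) at 1.5 mm. With 1 mismatch allowed in the core it had 8 to 42 reads per library, so its count depended on the matching rule. miR2275, which starts the 24 nt ones, had 4.31 to 10.5 RPM, with cold to control ratios of 1.19 (exact 95% interval 0.757 to 1.90) at 1.5 mm, 0.775 (0.547 to 1.09) at 2.2 mm and 1.25 (0.856 to 1.85) at 3.0 mm. No difference in either family was detectable at this depth.

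**Figure D2:**
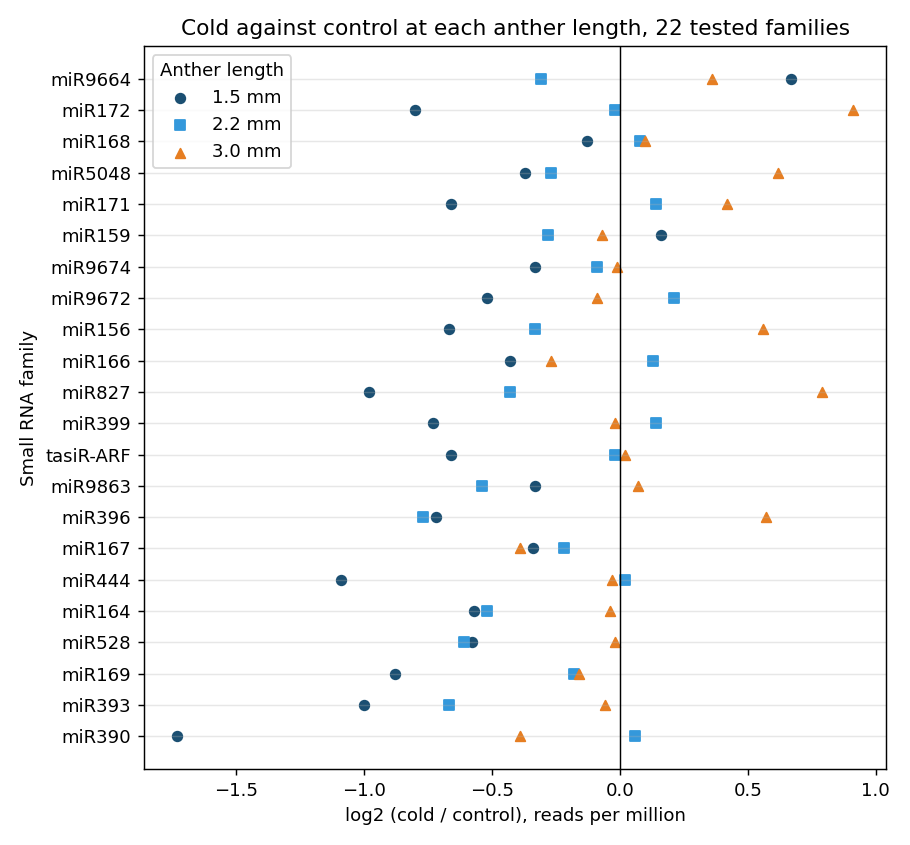
log2 ratio of cold to control RPM (horizontal axis) for the 22 tested families (vertical axis), 1 symbol per anther length, each from 1 cold and 1 control library, sorted by the mean of the 3 ratios. At 1.5 mm 20 of 22 symbols lie below 0, and miR390 lies lowest, at -1.73.

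The test had only the differences between stages as its spread (2 residual degrees of freedom for each family), partly pooled over the families by edgeR. For miR167 the SD of the 3 ratios was 0.09 and the SE of the estimate 0.17. For miR172 they were 0.86 and 0.37. On simulated counts the test recovered 48.0% of the families changed 2-fold and 99.0% of those changed 4-fold. TMM scaling moved the log2 ratios by 0.03, -0.21 and -0.11 at 1.5, 2.2 and 3.0 mm, which put 20, 22 and 15 of the 22 families lower in cold and turned ratios near 0, such as those of miR168 at 2.2 and 3.0 mm (to -0.13 and -0.01) and of miR390 at 2.2 mm (to -0.14), below 0.

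Within single stages the libraries were compared without a test, since each condition had 1 library. At 1.5 mm, 1 family differed by at least 2-fold beyond counting error: miR390 (leading sequence AAGCTCAGGAGGGATAGCGCC) had 252.8 RPM in the control and 76.3 in the cold library, a ratio of 0.302 (exact 95% interval 0.278 to 0.328). The control level at 1.5 mm stood out, as the other 6 libraries held 57.9 to 84.4 RPM of miR390. tasiR-ARF, downstream of miR390, had 527.6 RPM in the control and 334.0 in the cold library at 1.5 mm, a ratio of 0.633 (0.605 to 0.662). On the log2 scale this was -0.66, near the median of the 22 tested families in this pair (-0.62). The control libraries at 1.0, 2.2 and 3.0 mm held 479.2, 477.4 and 566.0 RPM of tasiR-ARF, so its level did not stand out as that of miR390 did. At 2.2 and 3.0 mm no family with 10 RPM or more differed by 2-fold beyond counting error. The intervals cover counting error and not the variation between plants. Matched on the full reference sequence instead, 2 families were at least 2-fold lower in cold at 1.5 mm.

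Sequence tags of 20 to 24 nt were compared in the same way, to include small RNAs outside the listed families. Of 7003 tags, 2 rose in cold and 0 fell (edgeR quasi-likelihood test, adjusted p below 0.05), with 197 at an unadjusted p under 0.05. The 22 nt tag TGGCGGAGCTGGTGGATGGATA rose by 2.44 ± 0.34 (SE) on the log2 scale, or 5.41-fold (edgeR adjusted p = 0.00326, higher in 3 of 3 pairs), with 30.2, 19.2 and 18.2 RPM in the cold libraries and 4.18, 3.35 and 4.65 in the controls at 1.5, 2.2 and 3.0 mm. The 21 nt tag TCTGGCTGGTAGAGCAGAGGA rose by 2.29 ± 0.33 (4.89-fold, edgeR adjusted p = 0.00326, higher in 3 of 3 pairs), with 28.4, 37.3 and 40.1 RPM in cold and 6.74, 5.90 and 9.12 in control. In the control library at 1.0 mm these tags had 10 and 33.6 RPM, so the level of the latter lay within the range of the cold libraries. All reads holding bases 3 to 18 of the 22 nt tag rose less than the tag, with log2 cold ratios of 1.08, 0.98 and 0.57. Those holding bases 3 to 18 of the 21 nt tag had 1.59, 1.64 and 1.86. The p-values of both tags rest on a spread partly pooled over the 7003 tags, not on their own ratios alone. Neither tag belonged to a listed family, and their places in the genome were not analysed here.

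At 1.5 mm the median log2 ratio of cold to control was -0.55 for 21 nt tags and 0.37 for 24 nt tags. At 2.2 mm it was 0.24 and 0.07, and at 3.0 mm 0.12 and 0.11, and the difference between the classes was not tested. Of 3849 tags of 24 nt, 1051 were higher and 104 lower in cold at all 3 stages, and 0 passed edgeR's test (145 had an unadjusted p under 0.05). Of 2259 tags of 21 nt, 89 were higher and 201 lower at all 3 stages. With TMM scaling the counts were 643 higher and 180 lower for 24 nt and 51 higher and 435 lower for 21 nt tags, and the median log2 ratio of 24 nt tags at 2.2 mm went from 0.07 to -0.14. Without the 1.5 mm pair 0 tags passed, although the estimates of both called tags stayed at 2.24 and 2.39. With all 7 libraries and anther length as a covariate 0 passed, with estimates of 2.20 and 1.73 for these tags, and DESeq2's Wald test on the 6 libraries called 5 (4 higher, 1 lower). The edgeR or DESeq2 adjusted p of the called tags ranged up to 0.559 and 1 over the alternatives.

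The next comparison asked which families changed with anther length from 1.0 to 3.0 mm, with cold as a covariate, over all 7 libraries. Both families that passed belong to the development list and rose. miR156 (leading sequence TGACAGAAGAGAGTGAGCAC), which targets SPL transcription factors, rose by 0.59 ± 0.17 (SE) log2 per mm (edgeR adjusted p = 0.0192, 0.0102 to 0.510 over all alternatives), from 935.9 RPM in the control at 1.0 mm to 1751 in the control and 2587 in the cold library at 3.0 mm. miR396 (leading sequence TCCACAGGCTTTCTTGAACTG), which targets growth-regulating factors, rose by 0.72 ± 0.24 log2 per mm (edgeR adjusted p = 0.0369, 0.00579 to 0.497 over all alternatives), from 131.1 to 279.7 in the control and 416.7 in the cold library. The development list thus had 2 members that rose and 5 that did not pass, and 2 passed when adjusted over the list alone. Slopes above 0 were common, in 20 of all 23 families, with 3 below 0.

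The other lists had no member past the threshold over all 23 families. miR393 of the auxin and stress lists had 0.67 ± 0.24 log2 per mm (edgeR adjusted p = 0.0579), and miR528 of the copper list had 0.51 ± 0.23 (edgeR adjusted p = 0.160). From 1.0 to 3.0 mm the control libraries held 151.0, 659.0, 471.2 and 635.7 RPM of miR528. Its level was thus low at 1.0 mm and already the highest of the controls at 1.5 mm, without a steady rise. Adjusted over the list alone, 1 of 5 auxin, 1 of 2 stress and 1 of 1 copper families passed, namely miR393 and miR528. miR393 is counted in both the auxin and the stress list. With 1 tested member the copper list makes no adjustment, so the p of miR528 there is unadjusted (edgeR, 0.0278). The families miR390 (-0.39 ± 0.26), tasiR-ARF (0.23 ± 0.21) and miR2275 (-0.27 ± 0.24 log2 per mm) did not pass, and with 1 library left out their slopes, where tested, were -0.65 to -0.09, 0.12 to 0.31 and -0.42 to -0.15. The 5 tested cereal families had slopes from 0.00 to 0.40 and the nutrient families miR399 and miR827 had 0.19 and 0.34, none past the threshold.

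The calls rested on few libraries. With the cold library at 3.0 mm left out, miR156 was at 0.41 log2 per mm and miR396 at 0.50, and 0 families passed. The threshold was also lost, with slopes of 0.49 to 0.58 for miR156 and 0.65 to 0.71 for miR396, without the 1.0 mm control, the 1.5 mm cold or the 2.2 mm cold library, and for miR396 without the 2.2 mm control (0.69). In the 4 control libraries alone 0 families passed, with slopes of 0.38 and 0.51. Without the 1.0 and 1.5 mm control libraries, which share the error A12C, miR156 (0.77) passed and miR396 (0.82) did not, and with a term for these libraries 0 families passed, with slopes of 0.82 and 0.88.

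**Figure D3:**
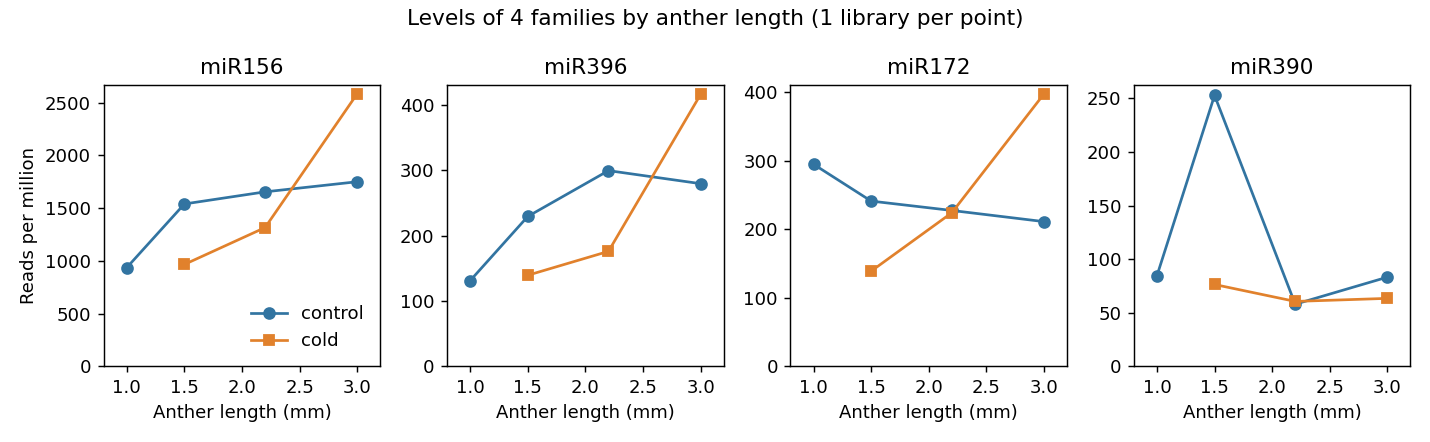
RPM (vertical axes, each from 0) of miR156, miR396, miR172 and miR390 against anther length in mm (horizontal axes), 1 library per point, control as circles and cold as squares. miR156 and miR396 were highest in the cold library at 3.0 mm (2587 and 416.7), and miR390 in the control library at 1.5 mm (252.8).

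Among 7589 tags, 1 rose with anther length: CGGACCAGGCTTCATTCCCC, which is the leading miR166 sequence TCGGACCAGGCTTCATTCCCC without its first base. It rose by 1.91 ± 0.27 (SE) log2 per mm (edgeR adjusted p = 0.0247), from 2.15 RPM in the control at 1.0 mm to 20.5 at 2.2 mm and 41.1 at 3.0 mm. The full-length form had 6535 RPM at 1.0 mm and 8343 in the control at 3.0 mm. In the control libraries the shortened form was thus at 0.0329, 0.0436, 0.395 and 0.493% of the full-length form from 1.0 to 3.0 mm. In the cold libraries it was at 0.135, 0.145 and 0.368% at 1.5, 2.2 and 3.0 mm. Without the 1.0 and 1.5 mm control libraries its slope was 1.28 and it did not pass (edgeR adjusted p = 0.999, against 1.03e-07 to 1 over all alternatives). The number of tags past the threshold depended on the libraries used: 341 (67 higher, 274 lower) in the 4 control libraries alone, 90 without the cold library at 1.5 mm, 7 and 5 without the cold library at 2.2 or 3.0 mm, and 0 without any 1 of the 4 control libraries. The slope of the shortened miR166 form stayed at 1.74 to 2.25 with any 1 library left out.

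The last comparison asked whether the cold effect changed as the anthers grew. For 1 of 23 families it did. The cold to control ratio of miR172 (leading sequence AGAATCTTGATGATGCTGCAT), which targets AP2-like genes of floral development, rose by 1.23 ± 0.23 (SE) log2 per mm (edgeR adjusted p = 0.0266). miR172 had 138.9 RPM in cold and 241.2 in control at 1.5 mm, 224.2 and 227.5 at 2.2 mm, and 397.9 and 211.2 at 3.0 mm. Of all 23 families, 18 had slopes above 0 and 5 below 0. Of the 7 tested members of the development list, 5 had slopes above 0 and 2 below 0, and miR172 alone passed. miR171 had 0.86 ± 0.28 (edgeR adjusted p = 0.144), miR156 0.57 ± 0.27 and miR396 0.56 ± 0.35, whereas miR166 had 0.17 ± 0.25, miR159 -0.00 ± 0.26 and miR164 -0.01 ± 0.50. miR827 of the nutrient list had 1.08 ± 0.29 (edgeR adjusted p = 0.0888, and 0.0154 adjusted over the list alone) and the cereal family miR5048 had 0.76 ± 0.26. The slopes of tasiR-ARF (0.43 ± 0.22), miR390 (0.34 ± 0.73) and miR2275 (0.58 ± 0.45) did not pass. With family reads as the library size miR172 had 1.06 and did not pass (edgeR adjusted p = 0.201, against 6.45e-07 to 0.703 over all alternatives), and it did not pass with any single library left out except the 1.5 mm control (slopes of 1.14 to 1.31). Without the 1.0 and 1.5 mm control libraries its slope was 1.15 (edgeR adjusted p = 0.0995).

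Beside these comparisons, 2 libraries stood apart from the rest in a way that the labels do not name. In the abundant miRNA sequences, the change A12C (positions counted from 1 at the 5' end of the miRNA) was read in 935 of 201883 reads, or 0.463% (95% Wilson interval 0.434 to 0.494%), in the control library at 1.0 mm and in 651 of 130246 reads (0.463 to 0.540%) in the control library at 1.5 mm. In each of the other 5 libraries it was read in 0.00644 to 0.0108% of the reads. The same 2 libraries had the lowest first principal component scores of the tags, -44.9 and -22.4, against -6.96 to 23.3 in the others (44.1% of the variance). On the second component (17% of the variance) they lay far from each other, at -14.2 and 29.7, against -15.9 to 9.43 in the others. The components thus did not place them together as a pair. Cold and control at 1.5 mm thus differed in this mark as well as in treatment, whereas the pairs at 2.2 and 3.0 mm did not.

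**Figure D4:**
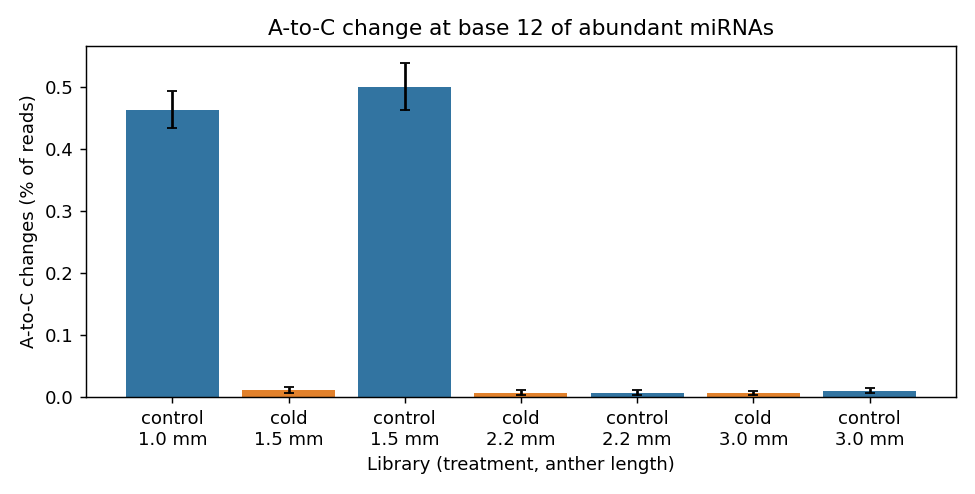
A-to-C changes at position 12 of abundant miRNA sequences (% of reads, vertical axis) in each of the 7 libraries, with 95% Wilson intervals that cover counting error. The control libraries at 1.0 and 1.5 mm had 935 and 651 such reads, and the other 5 libraries 14 to 19 each.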

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

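The tests in this part were chosen after the results were seen, except the tests of end bases and of A12C in other tags, which were set before their values were known; the bound that decides the latter was changed after its count was seen. The change of the cold ratio of miR172 with anther length was singled out because the cold effect differed between stages by a test of that difference (interaction 1.23 log2 per mm, edgeR adjusted p = 0.0266). A difference between sequencing runs is not excluded as a cause. In the 5 libraries without the error at position 12 the slope was 1.15 ± 0.43 (SE) log2 per mm (unadjusted p = 0.0231 in edgeR's test, adjusted p = 0.0995). Those libraries hold no control at 1.5 mm, so this slope does not use a cold ratio at that stage. Whether 1 sequence of the family made the change is only partly answered. From 1.5 to 3.0 mm the log2 cold ratio of the leading sequence moved by 1.79, and those of the next sequences, GGAATCTTGATGATGCTGCAT and GAATCTTGATGATGCTGCAT, by 1.07 and 1.98. The latter is the leading sequence without its first base, so its change may follow from that of the leading sequence. The former is a distinct sequence that moved the same way by less, at 14.5 RPM on average. The variation between single libraries stays open beside an effect of cold on the timing of miR172, because each ratio rests on 1 library per treatment.

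The 1.0 and 1.5 mm control libraries stood apart in A12C and in 18 tags above 5 RPM in both and below 0.5 RPM in the other 5. For each of the other 20 pairs of libraries there were 0 such tags. Of the 18 tags, 1 was an A12C copy of a tag over 50 times as abundant. The 2 libraries also had the lowest scores on the first principal component, but lay far from each other on the second (-14.2 and 29.7). For A12C itself, anther stage or a sequence variant is argued against, which leaves an error of the sequencing run: 80 of the 100 most abundant other tags with A there had it in over 0.2% of reads in both libraries, against at most 2 in any other library. The bound set beforehand was 90, but counting error at the rate of the miRNAs puts the number at 80.8, so 90 was too high for these depths, and the reading here rests instead on a bound of 50, against a lower 95% Wilson bound of 71.1% of the tags. For the first principal component and the remaining 17 tags, a difference between batches and the young stage of untreated anthers cannot be told apart. These are the only untreated libraries below 2.2 mm. The 3 bases at each end explained 9.82% of the variance of 24 nt tags, within the range of the other pairs (median 6.92%, highest 16.5%). RNA breakdown stays open too, since 0 of 9 tRNA and rRNA fragment classes (the 8 listed and the added wheat start of 5.8S rRNA) were higher in both libraries than the median of the other 5, whereas reads of 18 nt made up 2.14 and 3.804% of them against 1.15 to 1.73% of the others.

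miR390 was 3.00-fold higher in the control library at 1.5 mm than in the control library at 1.0 mm (exact 95% interval from 2.77, for counting error only). The 1.0 mm library carries the same error, so the libraries with the error did not share this level. They are single libraries that also differ in anther length, so a part of a shared run is not excluded. Whether a single variant rose cannot be decided. Of the 6 most abundant miR390 sequences, 5 were at least 2-fold above the median of the other 6 libraries. These sequences are the leading one and trimmed or extended forms of it, which would rise with it. The library size is argued against as the cause: the median family was 0.10 log2 units above the other libraries and miR390 was 1.86 above. Variation between samples stays open, since the level was seen in 1 library, beside a brief rise of miR390 in untreated anthers of that length.

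Other groupings of the 6 libraries were fitted with the stage term. There are only 10 splits of 6 libraries into 3 and 3, too few for a share under 0.05. With a real count of 0 families every split gave at least as many (10 of 10, highest other count 2), so the splits say nothing about families. For tags, 5 of the 10 splits gave at least the real count of 2. Of the 4 splits that keep the pairing, with 1 library of each stage on each side, 3 did, the real one included; the other 6 put both libraries of a stage on 1 side, and 2 of them did. The highest other count was 27, several times the real one, in a split that keeps the pairing (cold at 1.5 mm, control at 2.2 mm and cold at 3.0 mm against the rest). This points to some structure of the samples, whose source was not tested. The first side of that split had the higher 24 nt share at each stage. The shares were 64.9 against 51.1%, 61.2 against 58.0%, and 59.60 against 59.52%, so at 3.0 mm they hardly differed. Deviations of cold and control libraries correlated at -0.18, -0.27 and -0.09 for matched lengths of 1.5, 2.2 and 3.0 mm. Across lengths the correlation was 0.26 (cold 2.2 mm, control 1.5 mm), 0.20 (3.0, 2.2), 0.16 (1.5, 3.0), 0.09 (1.5, 2.2), -0.07 (2.2, 3.0) and -0.10 (3.0, 1.5). Libraries of matched length were thus not the most alike in this measure, on which no test was run.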

How the results depend on the processing

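All alternatives were set before the data were examined except those marked as added, which were chosen after seeing the data. Of the values of single families and tags under the alternatives, 210 kept their direction and side of the threshold, 39 lost the threshold, 1 gained it and 3 reversed. Of the counts and shares, 64 held, 47 moved and 4 reversed. A count was said to hold if it equalled the main count or lay within 1.5-fold of it, and a share if its mean difference kept its sign. Families called for cold numbered 1 with TMM factors (miR167) and 0 under the other alternatives (0 to 0 with a pair left out, though 6 had an unadjusted p under 0.05 without the 3.0 mm pair, against 0 in the main test and 4 with TMM factors). Tags called for cold numbered 5 with DESeq2's Wald test, 0 with all 7 libraries and anther length (estimates 2.20 and 1.73), and 0 to 6 with a pair left out; removing the 1.5 mm pair ended the calls. Families called for the trend numbered 3 with TMM factors, DESeq2 size factors or DESeq2's Wald test. They numbered 0 with family reads as library size, with the full reference or in the 4 controls, 1 with no filter, 1 and 0 without or with a term for the 2 libraries with A12C (added), and 0 to 4 with a library left out. Removing the 1.0 mm control or the cold library at 1.5, 2.2 or 3.0 mm ended both calls, and removing the 2.2 mm control ended that of miR396, while the slopes stayed at 0.41 to 0.58 for miR156 and 0.50 to 0.71 for miR396. Slopes were 0.77 to 0.88 in the fits added for A12C, 0.62 and 0.87 with the full reference, 0.59 and 0.72 with no filter, 0.45 and 0.58 with family reads as library size, and 0.38 and 0.51 in the 4 controls. Tags called for the trend numbered 2 with TMM or DESeq2 size factors, 7 with DESeq2's Wald test, 21 with a filter of 2 RPM, 341 in the 4 controls, 0 without or with a term for the 2 libraries (added), and 0 to 90 with a library left out (0 without any 1 control). The slope of the tag called in the main fit stayed at 1.74 to 2.25 with a library left out. Families called for the interaction numbered 0 with family reads as library size or the full reference, 3 with DESeq2's Wald test, 2 with no filter or 1 mismatch, 0 without or with a term for the 2 libraries (added), and 0 to 2 with a library left out (0 unless it was the 1.5 mm control). Within the 1.5 mm stage 2 families were called with the full reference. The trend of miR390 was 0.00 without and 0.24 with a term for the 2 libraries, and the cold estimate of tasiR-ARF was -0.34 to 0.00 with a pair left out. With a pair left out the mean differences in share were -3.31 to 1.71 points for 21 nt, -1.53 to 6.96 for 24 nt, -0.230 to 0.006 for fragments and -1.64 to 1.11 for distinct sequences, reversed without the 1.5 mm pair; the 22 nt and family shares stayed below 0. With the wheat start of 5.8S rRNA (added) the mean for fragments was -0.298, and at equal depth (added) the mean for distinct sequences was 1.08. The full reference tested 18 families and left-out libraries lowered the degrees of freedom; otherwise the cause was not tested. Low read counts limited families under 10 RPM, such as miR2118, whose counts also depended on the matching rule.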

Other observations

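Below the level needed for the test, several families had a cold to control ratio below 1 at 1.5 mm and above 1 at 3.0 mm with intervals that did not overlap. miR319, which targets TCP transcription factors, had a ratio of 0.0800 (exact 95% interval 0.0280 to 0.186) at 1.5 mm, from 6 and 51 reads, 1.24 (0.834 to 1.86) at 2.2 mm and 2.50 (1.70 to 3.74) at 3.0 mm. miR1432 had 0.367 (0.234 to 0.565), 0.663 (0.449 to 0.969) and 2.39 (1.60 to 3.63). miR395, which acts in sulphate nutrition, had 0.481 (0.288 to 0.792), 0.515 (0.235 to 1.07) and 4.89 (2.28 to 12.03). miR160, which targets auxin response factors, had 0.258 (0.116 to 0.531), 1.14 (0.666 to 1.95) and 1.43 (0.937 to 2.20). The intervals overlapped for miR394, at 1.02 (0.324 to 3.48), 1.09 (0.520 to 2.31) and 3.56 (1.61 to 8.94), and for miR398, a copper-regulated family, at 1.41 (0.861 to 2.38), 1.40 (0.876 to 2.27) and 1.60 (1.12 to 2.31). The change of these ratios between stages was not tested. These families were chosen after their values were seen, and the ratios compare single libraries.

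Several families were read mainly in sequences other than their listed references. The leading miR159 form was the 18 nt TTTGGATTGAAGGGAGCT, with 50.8 to 74.6 RPM, against 3.38 to 7.24 for the 21 nt form. The 22 nt form of miR167, TGAAGCTGCCAGCATGATCTGA, exceeded the 21 nt form TGAAGCTGCCAGCATGATCTA by 1.74 and 1.68 times in the 1.0 and 1.5 mm control libraries, 2.47 times in cold at 2.2 mm, and 3.36 to 3.54 times in the other 4. These 2 miR167 sequences end in GA and in A after the same bases. The shorter one is thus not a trimmed copy of the longer one. The tRNA-His fragment was at 97.8 RPM in cold at 1.5 mm and at 30.1 to 54.8 in the other 6 libraries. Reads holding bases 3 to 18 of TCTGGCTGGTAGAGCAGAGGA, one of the tags that rose in cold, had log2 cold ratios of 1.59, 1.64 and 1.86, and those of TGGCGGAGCTGGTGGATGGATA had 1.08, 0.98 and 0.57. The most abundant neighbour of either tag at 1 mismatch had 0.228 RPM or fewer on average.

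One hypothesis was that spikes in the cold may keep the small RNA profile of a younger anther at a given anther length. Its test was set before its values were known. It correlated, across 7589 tags and with no library shared, the log2 cold ratio at 2.2 mm with the log2 ratio of the 1.0 to the 3.0 mm control, and the log2 cold ratio at 3.0 mm with that of the 1.0 to the 2.2 mm control. The correlations were 0.02 and 0.14, too small and uneven to decide it. In the 4019 tags of 24 nt, looked at afterwards, they were 0.48 and 0.24, and in the 2652 tags of 21 nt -0.04 and 0.05. Tags are not independent replicates, and the 1.0 mm library carries the error at position 12, so the 24 nt values remain a hint for a hypothesis and not a result.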
